A study of Anopheles gambiae with 15 samples.

How the data were processed

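Messenger RNA levels were measured in 4 sections of the gut of 4th instar larvae of the malaria mosquito Anopheles gambiae, G3 strain, and in whole larvae of the same stage. Per the labels' protocols, larvae were reared in water at 28 °C on yeast and ground fish food, and guts were dissected in ethanol and divided into gastric caeca, anterior midgut, posterior midgut, and hindgut with the Malpighian tubules. Each gut-section array holds pooled material of 1000 dissected guts and each whole-larva array holds 200 individuals, per the labels. Total RNA was turned into biotin-labelled cRNA with a one-cycle Affymetrix labelling kit and hybridized to an oligonucleotide array on which each transcript is read by a set of short probes. Each of the 5 groups has 3 arrays, which the labels call biological repeats, and 15 arrays were used in all.

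The values analysed are the deposited log2 expression values, 1 per probe set and array. They were made with RMA per the submitters' processing notes, a method that corrects background, normalizes probe intensities between arrays and summarises the probes of a set. The version and settings of RMA are not given in the sources used here. The log2 scale was read from the values themselves, which run from 3.13 to 14.4 with array medians of 4.56 to 4.85. RMA draws low signals towards a common floor, so that folds of dim probe sets are understated. The number of arrays limits the precision of these values, and an array gives no counting depth.

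The table holds 22761 probe sets. Those whose ID starts with Ag, 16884 in number, were tested as the mosquito probe sets, and the 4506 with IDs starting with Pf were taken as probe sets of a malaria parasite absent from these larvae, by a rule on ID prefixes. No source used here states the organism of an ID. Another 290 IDs start with a number, 937 with a sequence accession and 144 with the prefix of the maker's controls, and these were left out of the tests. Files and tables used here do not pair probe set IDs with genes, and the RefSeq gene table for assembly idAnoGambNW_F1_1 matched 0 of the IDs. Gene names, gene lists and set tests on them are therefore not used here, and probe sets appear under their IDs. At most 2 IDs that rose and 2 that fell are printed per comparison. They are those with the largest change past the threshold whose 3 section arrays all lay on the same side of all 3 whole-larva arrays. Per section over the other sections, the 2 IDs with the widest gap to the nearest other section are printed. This is the ranking fixed for named genes, applied to probe sets.

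A linear model with a mean per group was fitted to all 15 arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes and no other covariate. All groups shared 1 estimate of the spread per probe set, with 2.76 prior degrees of freedom. The 4 comparisons of a section with whole larvae and the 6 between sections were contrasts of this fit, and every adjusted p below is limma's after Benjamini-Hochberg adjustment within a contrast. A probe set was called at an adjusted p under 0.05 and a difference of at least 2-fold. A probe set was counted as highest in a section when it passed in all 3 contrasts with the other sections. Errors of differences are limma's standard errors, and errors of levels are standard deviations over 3 arrays. Single measures of arrays were compared with two-sided exact permutation tests, whose smallest p for 3 arrays against 3 is 0.1. The groups, tests, thresholds, the background rule and most alternative settings were chosen before the data were examined. The same fit was tested on simulated data over 16884 probe sets. All 15 arrays were simulated from the mean and the pooled spread of each probe set, and known changes were added to the hindgut arrays. Against whole larvae, the fit called 86% of the probe sets raised by 1.5 on the log2 scale and 98% of those raised by 2. It called 92% of those lowered by 2, with 5 false calls. The groups differ in their spread, and unchanged groups simulated with the spread of each group gave 38.2 calls per comparison.

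A probe set was taken as above background in a group when its mean exceeded the 95th percentile of the Pf probe sets, which lay between 3.96 and 4.10. The 95th percentile of the IDs that start with a number lay higher, between 5.29 and 5.83, and was added as a second background after the values were seen.

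The labels' protocol divides the guts of each repeat into the 4 sections, but does not state that arrays with the same number come from the same repeat. Deviations of same-numbered arrays from their group means were correlated across probe sets. All 3 correlations were over 0.1 for caeca with whole larvae (0.268 to 0.350), posterior midgut with whole larvae (0.172 to 0.257) and caeca with posterior midgut (0.300 to 0.350), and these pairs were taken as paired. In the other 7 comparisons at least 1 correlation was below 0.1, down to -0.344. Adding the replicate number as a block gave 737 probe sets higher and 676 lower in caeca than in whole larvae, 631 and 881 in posterior midgut, and 445 past the threshold between caeca and posterior midgut.

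Alternatives were the replicate block, the plain t-test of the study's design with and without adjustment, fits of only the groups compared, a trended robust variance prior, quantile normalization of the values again, median centring, a background filter, array weights, other fold thresholds and leaving out each array in turn. Array weights were estimated gene by gene, since the default estimate did not converge. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.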

Results

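RNA from 4 gut sections and from whole 4th instar Anopheles gambiae larvae was profiled on 15 arrays, 3 for each of 5 groups. The gastric caeca are blind pouches at the front of the larval midgut, the anterior and posterior midgut are the tube behind them, and the hindgut sample includes the Malpighian tubules, the excretory organs of insects. The design asked which transcripts are enriched in each section relative to whole larvae. Whole larvae also contain the gut, so a section is compared with a mixture that holds some of its own RNA.

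Arrays of gastric caeca correlated with each other at r = 0.979 to 0.984 across the 16884 tested probe sets, those of posterior midgut at 0.977 to 0.982 and those of hindgut at 0.981 to 0.987. These correlations are across probe sets, which are not independent replicates. Anterior midgut arrays correlated at 0.871 to 0.964 and whole-larva arrays at 0.927 to 0.947. The root mean square SD within a group was 0.237 log2 units in hindgut, 0.242 in caeca and 0.252 in posterior midgut, against 0.442 in whole larvae and 0.470 in anterior midgut. The first principal component held 35.6% of the variance and separated hindgut from the 3 other sections. The second, with 21% of the variance, separated whole larvae from all sections.

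**Figure D1:**
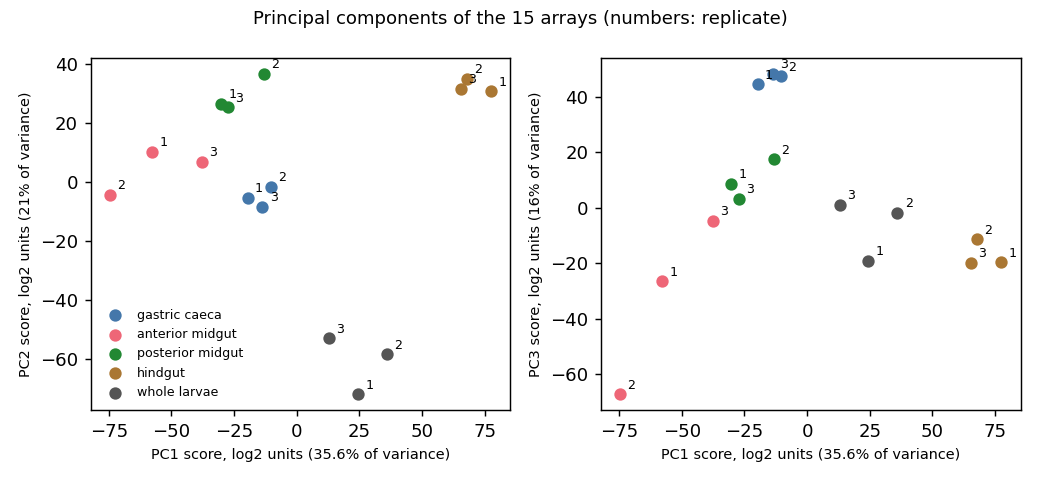
Scores of the 15 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in log2 units, with a point per array coloured by group and numbered by replicate. Hindgut arrays score 65.5 to 77.6 on the first component, and anterior midgut array 2 scores -74.7, the lowest of all arrays.

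Control probe sets differed between arrays in ways that moved with a group. The 3' minus 5' level of the actin and Gapdh control probe sets, a measure of how far a labelled RNA is biased to the 3' end of transcripts, averaged 0.93 ± 0.15 (SD, n = 3) log2 units in whole larvae. It was 0.83 ± 0.21 in caeca, 0.90 ± 0.19 in anterior midgut and 0.96 ± 0.26 in posterior midgut. In hindgut it was 0.08 ± 0.26, below every other array (exact permutation p = 0.1 against whole larvae, n = 3 per group, the smallest p this design allows). The level of the added bioC spike minus that of the cre spike followed the replicate number in the other 4 groups, at -4.31 to -4.68 for replicate 1, -3.80 to -4.49 for replicate 2 and -2.82 to -3.26 for replicate 3. The 3 hindgut arrays lay at -3.21 to -3.37, an SD of 0.09 against 0.70 to 0.96 in the other groups, with caeca array 3 among them at -3.26. The ranges of replicates 1 and 2 overlap, and no batch is given in the sources used here. Anterior midgut array 2 had the lowest median spike level, 6.94, against 8.01 and 9.89 in anterior midgut arrays 1 and 3.

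**Figure D2:**
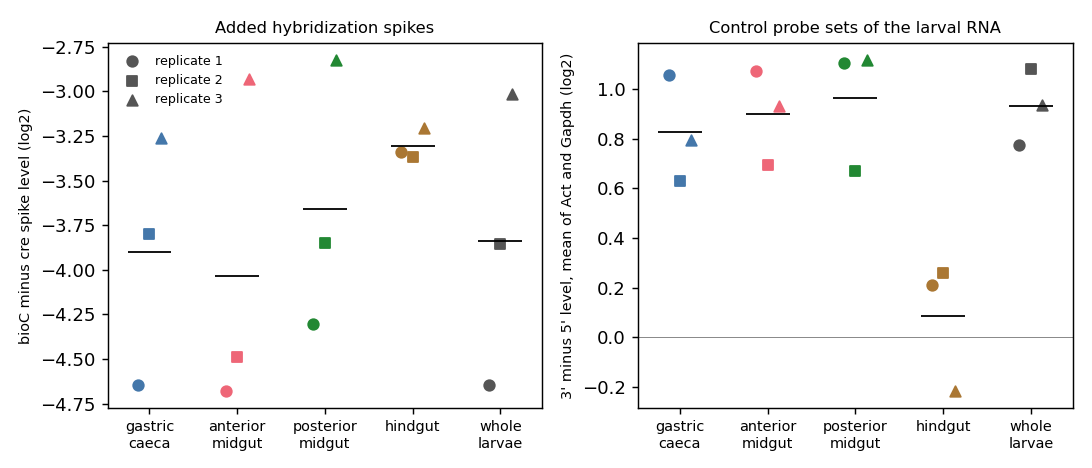
Level of the bioC spike minus the cre spike (left) and mean 3' minus 5' level of the actin and Gapdh control probe sets (right), in log2 units, per array; the marker shape gives the replicate number and the line the mean of the 3 arrays. The 3 hindgut arrays lie together on the left, and on the right they lie between -0.22 and 0.26 while all other arrays lie at 0.63 or above.

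By the Pf background, 92.8% of the tested probe sets were above background in hindgut, 93.9% in posterior midgut, 94.2% in anterior midgut, 94.5% in caeca and 96.1% in whole larvae. Against the higher background of IDs that start with a number, 7612 probe sets were above background in whole larvae, 7185 in hindgut, 6958 in caeca, 6005 in posterior midgut and 4676 in anterior midgut. That background is set per group and lay highest in anterior midgut, at 5.83, against 5.29 to 5.56 in the other groups. The groups were therefore not counted at the same level. By that background 4183 probe sets were detected in all 5 groups, 1069 in at least 1 section but not in whole larvae, and 564 in whole larvae but in no section. The same limit applies to these counts.

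In gastric caeca 716 probe sets were higher than in whole larvae and 659 were lower. The median change was 3.27-fold among the higher and 3.65-fold among the lower probe sets, and 240 higher and 303 lower ones changed at least 4-fold. The largest rise was that of Ag.2L.586.1_a_at, at 11.55 ± 0.81 (SD, n = 3) in caeca and 6.91 ± 2.37 in whole larvae, 24.9-fold (adjusted p = 0.0045), or 15.5-, 64.4- and 15.6-fold without whole-larva arrays 1, 2 and 3. Ag.2L.1688.1_CDS_at was 20.7-fold higher in caeca (adjusted p = 8.9e-05), 12.9-fold without whole-larva array 1, and lay at 4.62 ± 0.07 in posterior midgut and 5.06 ± 0.73 in hindgut. The largest fall, 139-fold, was that of Ag.2R.18.0_CDS_at, which stood at 12.02 ± 0.42 in whole larvae (adjusted p = 1.2e-10). Its level in each section lay below the higher background, so its folds are not exact. Ag.2R.1003.0_CDS_at was 69.5-fold lower (adjusted p = 2.8e-08). Of all tested probe sets, 15% had all 3 caeca arrays above all 3 whole-larva arrays and 12.5% had them below, where chance alone gives 10% for both directions together. Within each replicate number the difference ran in the same direction for 716 of the higher and 657 of the lower probe sets. These probe sets were chosen on the same arrays, and 711 and 642 of them had all 3 caeca arrays beyond all 3 whole-larva arrays. Agreement within replicate numbers was therefore largely set by the choice, here and in the other sections.

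In anterior midgut 396 probe sets were higher than in whole larvae and 1343 were lower. Higher ones thus made up 22.8% of the calls, and 45.1% (939 higher, 1143 lower) when the values were quantile normalized again. Ag.3R.871.0_CDS_at was 22.8-fold higher, at 9.87 ± 0.64 (SD, n = 3) against 5.36 ± 0.35 in whole larvae (adjusted p = 6.3e-05). Ag.3L.444.0_CDS_at was 19.6-fold higher, at 11.18 ± 0.38 against 6.89 ± 0.40 (adjusted p = 1.7e-06), and lay at 9.06 ± 0.65 in caeca and 4.30 ± 0.14 in hindgut. Ag.2R.18.0_CDS_at was again the probe set with the largest fall, 136-fold, followed by Ag.3R.169.0_CDS_s_at with 129-fold (adjusted p = 6.5e-07), both with an anterior midgut level below the higher background. Of the lower probe sets, 582 changed at least 4-fold and 197 at least 10-fold; of the higher ones, 113 and 17 did. Within each replicate number the difference ran in the same direction for 384 of the higher and 1315 of the lower probe sets. Anterior midgut array 2 had a narrower range of values than the other arrays, with an SD over tested probe sets of 1.40 log2 units against 1.59 to 1.85. Without array 3 there were 647 higher and 1771 lower probe sets, and without array 2 there were 517 and 1048. With only anterior midgut and whole-larva arrays in the fit there were 161 and 536. Fits of only the 2 groups compared gave 625 and 450 in caeca, 526 and 614 in posterior midgut and 1208 and 507 in hindgut. Anterior midgut and whole larvae had the widest root mean square SDs, 0.470 and 0.442 against 0.237 to 0.252. On average, the spread shared by all 5 groups is thus too small for this comparison. Its reported counts and adjusted p-values are therefore likely too favourable.

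In posterior midgut 628 probe sets were higher than in whole larvae and 873 were lower. The median change was 3.32-fold among the higher and 4.20-fold among the lower probe sets. Ag.2L.2564.0_CDS_at was 17.9-fold higher, at 9.58 ± 1.51 (SD, n = 3) against 5.42 ± 0.15 in whole larvae (adjusted p = 0.0012), or 10.7- and 30.4-fold without posterior midgut arrays 1 and 3. Ag.2R.2849.0_CDS_at was 17-fold higher, at 12.04 ± 0.19 against 7.96 ± 1.82 (adjusted p = 0.0024), or 8.25- and 26.4-fold without whole-larva arrays 1 and 2. Ag.2R.18.0_CDS_at fell 117-fold and Ag.UNKN.46.0_UTR_a_at 114-fold (adjusted p = 1.9e-10 and 1.8e-06), both to levels below the higher background. At least 4-fold changes were found for 221 higher and 452 lower probe sets, and at least 10-fold changes for 19 higher and 197 lower ones. Of all tested probe sets, 16.6% had all 3 posterior midgut arrays above all 3 whole-larva arrays and 12.8% had them below, against 10% by chance for both directions together. Within each replicate number the direction was the same for 628 of the higher and 867 of the lower probe sets.

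In hindgut with Malpighian tubules 1230 probe sets were higher than in whole larvae and 683 were lower. Ag.2L.211.0_CDS_at was 45.9-fold higher, at 11.79 ± 0.08 (SD, n = 3) against 6.27 ± 1.71 in whole larvae (adjusted p = 4.6e-05). Ag.3L.257.0_CDS_at was 38.8-fold higher, at 11.89 ± 0.09 against 6.61 ± 1.98 (adjusted p = 2e-04). Without whole-larva arrays 1 and 2 these were 26.9- and 86.8-fold for the first and 21.3- and 82.1-fold for the second. Ag.2R.18.0_CDS_at fell 198-fold, to a level below the higher background. Ag.2L.1725.0_CDS_at fell 160-fold, from 13.38 ± 0.20 in whole larvae to 6.06 ± 0.21, while it stood at 14.33 ± 0.10 in caeca. Higher probe sets made up 64.3% of the hindgut calls, 54.9% (879 higher, 721 lower) when the values were quantile normalized again and 69.5% when each array was centred on its median. At least 10-fold changes were found for 82 higher and 81 lower probe sets. Within each replicate number the difference ran in the same direction for 1226 of the higher and 667 of the lower probe sets. The 3' minus 5' level given above was lower in the hindgut arrays than in all others.

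**Figure D3:**
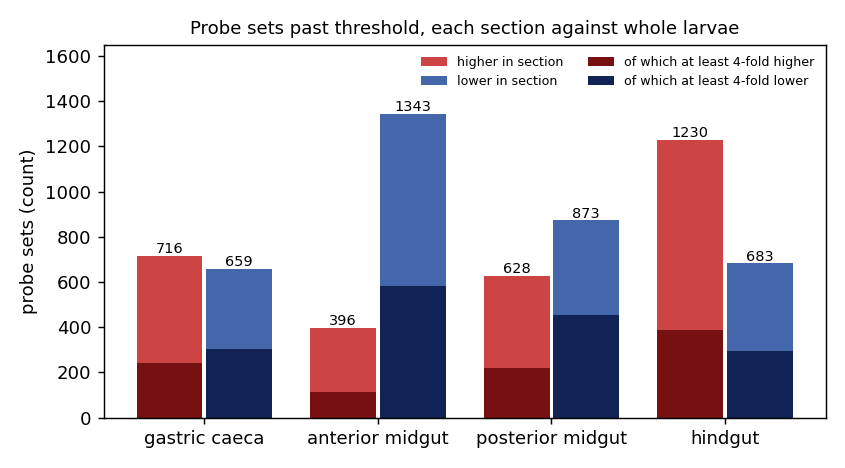
Number of probe sets past the threshold (limma adjusted p under 0.05 and at least 2-fold) for each section against whole larvae, higher in red and lower in blue, with the darker part of each bar showing those changed at least 4-fold. Lower probe sets outnumber higher ones in anterior midgut (1343 against 396) and higher ones outnumber lower ones in hindgut (1230 against 683).

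Some ID stems carry both a probe set with CDS in its ID and a probe set with UTR in its ID, and 728 stems did so here. No source used here defines these ID fields, but the profiles of such partners correlated at a mean r of 0.564 over the 15 arrays, against 0.0773 for random pairs. In hindgut, 131 of these CDS probe sets were higher than in whole larvae and 37 lower, whereas 54 of their UTR partners were higher and 65 lower. In caeca the CDS probe sets gave 64 higher and 43 lower calls, and the UTR partners 26 and 74. Higher calls were a larger share of the calls among CDS than among UTR probe sets in all 4 sections, by 33.8 percentage points in caeca, 14.1 in anterior midgut, 16 in posterior midgut and 32.6 in hindgut (Fisher's exact test, adjusted over 4 sections, p = 3e-06, 0.0017, 0.01 and 9.6e-08). Probe sets are not independent, and the test ignores that each CDS probe set has a UTR partner, so these p-values compare the counts and not the larvae. All 4 comparisons use the same whole-larva arrays, so their agreement is not that of 4 separate results.

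**Figure D4:**
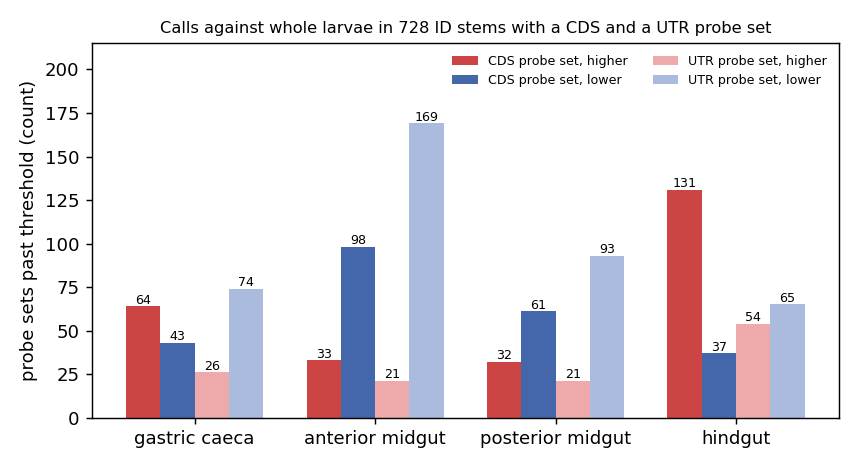
Number of probe sets past the threshold against whole larvae in 728 ID stems that have both a CDS and a UTR probe set, by section, with CDS probe sets in dark and UTR probe sets in light colours, higher in red and lower in blue. In hindgut the CDS probe sets give 131 higher and 37 lower calls and the UTR probe sets 54 and 65.

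Over the 4 comparisons with whole larvae, 1931 probe sets (11.4%) were higher in at least 1 section and 1637 (9.7%) were lower in at least 1, while 13678 (81%) passed in none. Of the higher probe sets, 1243 passed in a single section, 392 in 2, 241 in 3 and 55 in all 4. Probe sets higher in hindgut and without a call in the other sections formed the largest class of calls, with 676. Of the lower ones, 693 passed in a single section and 302 in all 4, among them Ag.2R.18.0_CDS_at. The number higher in all 4 sections was 96 without anterior midgut array 2 and 33 without whole-larva array 1.

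Caeca and posterior midgut shared 375 of their higher probe sets, 59.7% of the shorter list, where independent lists would share 26.6. Anterior and posterior midgut shared 202 (14.7 for independent lists), caeca and anterior midgut 192 (16.8), caeca and hindgut 303 (52.2), posterior midgut and hindgut 270 (45.7), and anterior midgut and hindgut 103 (28.8). As a share of the shorter list, lower probe sets overlapped more, with 779 shared by anterior and posterior midgut (69.4 for independent lists), 89.2% of that list. Unchanged groups simulated against the same whole-larva arrays shared 0.02 or fewer probe sets with a pooled spread and 5.9 to 7.44 with the spread of each group, from 38.2 calls per comparison, too few to compare with lists of the size found here. The covariance of the fold changes over all tested probe sets was 0.519 for anterior and posterior midgut, 0.427 for caeca and posterior midgut and 0.193 for anterior midgut and hindgut, against about 0.0345 simulated for shared whole-larva arrays with the pooled spread and 0.066 with their own, larger one. Taken against different whole-larva arrays, 1 for a section and 2 for the other, these covariances averaged 0.454, 0.362 and 0.128 over the 6 assignments. A split of 3 arrays leaves 1 of them alone, so the lists of calls were not split, and part of the excess over independent lists may come from the shared controls.

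Compared directly, caeca and posterior midgut gave the fewest calls of the 6 pairs of sections in this fit, with 413 probe sets past the threshold, 283 of them higher in caeca. Anterior and posterior midgut differed at 545, of which 462 were higher in posterior midgut, and caeca and anterior midgut at 781, of which 675 were higher in caeca. Hindgut differed from posterior midgut at 1686 probe sets, from caeca at 1431 and from anterior midgut at 2551. Without anterior midgut array 3 the counts were 1775 between caeca and anterior midgut and 1304 between anterior and posterior midgut. The root mean square log2 difference, corrected for the spread between replicates, was 0.509 between anterior and posterior midgut, 0.550 between caeca and posterior midgut and 0.652 between caeca and anterior midgut. It was 0.798, 0.853 and 0.969 between hindgut and posterior midgut, caeca and anterior midgut. The order of the 2 closest pairs was not settled, since leaving out 1 array in turn gave 0.441 to 0.615 for the anterior and posterior midgut and 0.538 to 0.571 for the caeca and posterior midgut.

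Probe sets higher in a section than in each other section numbered 136 in caeca, 54 in anterior midgut, 26 in posterior midgut and 814 in hindgut. In caeca, Ag.3L.687.0_CDS_at stood at 12.55 ± 0.09 (SD, n = 3), 190-fold above anterior midgut, the nearest section (adjusted p = 8.7e-09), and Ag.3L.2015.0_CDS_at at 12.91 ± 0.17, 187-fold above posterior midgut (adjusted p = 1.2e-11). Both were also present in whole larvae, at 10.61 ± 0.40 and 10.86 ± 0.03. In anterior midgut, Ag.3L.1883.0_CDS_at led caeca by 6.87-fold and Ag.3L.1555.0_CDS_at by 5.44-fold (adjusted p = 0.00023 and 0.00049). In posterior midgut, Ag.3R.2365.0_CDS_at stood at 11.20 ± 0.96 and led anterior midgut by 40.1-fold (adjusted p = 0.0074; 68-fold without anterior midgut array 3), and Ag.2L.2540.0_CDS_at led it by 24.2-fold (adjusted p = 0.0034). In hindgut, Ag.3R.478.0_CDS_at stood at 12.61 ± 0.22, 69.3-fold above posterior midgut (adjusted p = 0.00026), or 41.8- and 128-fold without posterior midgut arrays 1 and 2, and Ag.2L.400.0_CDS_at at 11.09 ± 0.32, 68.1-fold above anterior midgut (adjusted p = 1.1e-08). The nearest section lay below the higher background for Ag.3L.687.0_CDS_at, Ag.3L.2015.0_CDS_at, Ag.3L.1555.0_CDS_at, Ag.2L.2540.0_CDS_at and Ag.2L.400.0_CDS_at, so these folds are not exact.

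**Figure D5:**
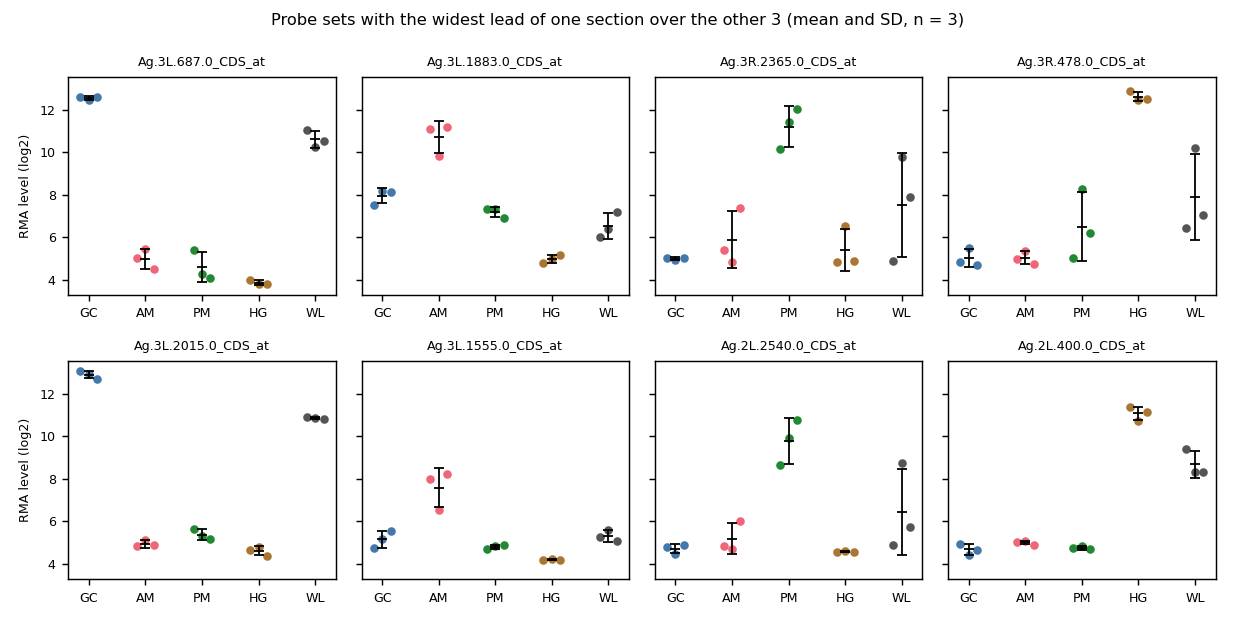
RMA level (log2) of the 2 probe sets with the widest lead in each section, a section per column, plotted for hindgut (HG), posterior midgut (PM), anterior midgut (AM), caeca (GC) and whole larvae (WL); points are arrays, bars the mean and SD of 3. The caeca probe sets stand at 12.55 and 12.91 in caeca and at 3.85 to 5.36 in the other sections.

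Most of these probe sets, highest in a section, were also higher than in whole larvae: 116 of 136 in caeca, 52 of 54 in anterior midgut, 24 of 26 in posterior midgut and 548 of 814 in hindgut. The median lead over the nearest section was 4.79-fold in caeca, 2.96-fold in anterior midgut, 3.51-fold in posterior midgut and 3.23-fold in hindgut. For the caeca probe sets the nearest section was anterior midgut for 53, posterior midgut for 54 and hindgut for 29. The opposite class, lower in a section than in each other section, held 221 probe sets in anterior midgut, 133 in hindgut, 13 in caeca and 3 in posterior midgut. Without array 3 of anterior midgut 204 probe sets were highest there, and without array 2 of posterior midgut 17 were highest in posterior midgut.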

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

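The tests of the spikes, of the 3' minus 5' level and of leaving out arrays 1 and 3 in turn in anterior midgut, of CDS against UTR probe sets in every section and between replicate numbers were chosen after the data were seen.

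Several probe sets lay on opposite sides of whole larvae in 2 sections, with both differences and the direct difference between the sections past the threshold in limma. Anterior midgut and hindgut held 228 of them, 181 lower in anterior midgut and higher in hindgut. Caeca and hindgut held 148, caeca and anterior midgut 126 (121 higher in caeca), posterior midgut and hindgut 88, anterior and posterior midgut 68 (65 higher in posterior midgut), and caeca and posterior midgut 60. These counts and their directions depend on the lengths of the lists, with 1343 lower and 396 higher in anterior midgut and 1230 higher and 683 lower in hindgut. On quantile normalization again the lists held 1143 and 939, and 879 and 721. Counts for independent lists were not computed for this class.

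Signals above whole larvae also appeared among probe sets left out of the tests. In caeca 2 probe sets with Pf IDs were higher, Pf.5.314.0_CDS_at by 1.70 and Pf.7.226.0_CDS_s_at by 1.27 on the log2 scale (limma adjusted p = 9.7e-06 for each), named here after their values were seen. In anterior midgut 3 probe sets with IDs that start with a number were higher, by 1.08 to 1.14, as were 1 with an accession ID, by 2.93, and 1 control, by 1.23. In posterior midgut 1 accession ID was higher, by 2.67. Lower calls in these classes were accession IDs, 4 in caeca, 5 in anterior midgut, 4 in posterior midgut and 5 in hindgut, with 1 Pf ID in hindgut and 1 control in anterior midgut.

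Anterior midgut array 2 stood apart from arrays 1 and 3 of its group, and degraded RNA would raise its 3' minus 5' level, which was lower by 0.237 log2 units (a difference of -0.237). This does not settle the point, since a compressed range of values, left open below, would also shrink that level. Less tissue of other sections would raise the probe sets that are highest in anterior midgut and lower those highest in posterior midgut, and the medians in array 2 differed by -0.771 (95% bootstrap interval -1 to -0.546) and -0.757. This stays open, since the sets were chosen on arrays 1 and 3, and the same choice made without array 3 gave -1.12 for that array and without array 1 gave 0.318. Array 3 also lay higher on the sets of posterior midgut (0.438), caeca (0.288) and hindgut (0.221) chosen without it. Each array is compared with the mean of the others of its group, so these values do not tell whether array 2 or array 3 is the one apart. Weaker hybridization of array 2 stays open too. Its spikes differed by -1.07 from the lower of arrays 1 and 3, but those of posterior midgut array 2 by -1.14 in a group whose arrays correlated at 0.977 to 0.982. That array 2 of other groups had to differ less was a condition added after these values were seen. A compressed range stays open too, since its slope on the other groups was 0.689, a difference of -0.184 from the lower slope of the other arrays, but a low correlation also lowers a slope; a true difference between pools of larvae was not tested.

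The excess of higher over lower probe sets in hindgut has technical and biological explanations that these arrays do not separate. The UTR partners of CDS probe sets called higher in hindgut moved by 0.554 of the CDS change at the median (bootstrap interval 0.483 to 0.681), an interval wholly above the 0.25 set for a bias of RNA integrity but reaching below the 0.5 set against it. The CDS probe sets were chosen as higher in these same arrays, which lowers this ratio whatever the RNA integrity. The ratio was not computed in another section, so it does not decide. Higher calls made up 78% of the calls among CDS and 45.4% among UTR probe sets, a difference of 32.6 points, as weaker 3' bias in hindgut could give, but it was 33.8 points in caeca, whose 3' minus 5' level was close to that of whole larvae; that other sections had to differ less was a condition added after these values were seen. The median shift of CDS over UTR partners was 0.40 (bootstrap interval 0.36 to 0.45) in hindgut, 0.37 in anterior midgut, 0.20 in caeca and 0.17 in posterior midgut, so this stays open. Replicate numbers of the other 4 groups differed at 0 probe sets in limma (1053 to 1709 at an unadjusted p under 0.05, and 39 at most without anterior midgut array 2) against 1913 for hindgut, but whether hindgut arrays were hybridized apart is not given in the sources used here and stays open, as does, untested, a larger set of transcripts particular to hindgut and Malpighian tubules.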

How the results depend on the processing

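Some settings were added after the data were seen: each array left out for the number shared by all sections and for distances, anterior midgut array 2 left out of every fit, other ID classes tested or used as background, and the replicate block without hindgut arrays. Of the counts recomputed, 307 stayed within 1.5 times the reported value and 55 did not. All 330 recomputed values of named probe sets kept their direction and their side of the threshold. Leaving out 1 array moved some of their folds by over 1.5 times, as given with them. Named probe sets were not recomputed with the t-tests, with only the compared groups or at other fold thresholds. They were chosen as the largest changes in these same arrays, which favours such stability. Gene list tests, a single probe set per gene and centring on ribosomal protein genes were not run. Signal over background limits dim probe sets, whose folds are compressed.

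The replicate block changed no count by more than 1.5 times, with 1241 higher and 702 lower in hindgut and 396 and 1356 in anterior midgut, where not all correlations of same-numbered arrays passed 0.1; 10 of 15 arrays correlated best with their own number.

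Quantile normalization again gave 939 probe sets higher in anterior midgut than in whole larvae (396 reported) and 104 highest there (54); the distances from hindgut fell to 0.725 from whole larvae, 0.813 from caeca, 0.9 from anterior midgut and 0.751 from posterior midgut. Without a fold threshold, 1503 were higher in anterior midgut, and 2027 higher and 1511 lower in hindgut. Counts follow from the threshold itself, also at 4-fold, but the share of higher calls moved with it as well. Without a fold threshold this share was 49% in caeca, 43.8% in anterior midgut, 43.2% in posterior midgut and 57.3% in hindgut. In the same order it was 44.2%, 16.3%, 32.8% and 56.9% at 4-fold, against 52.1%, 22.8%, 41.8% and 64.3% reported. At 4-fold, higher and lower counts were 240 and 303 in caeca, 113 and 582 in anterior midgut, 221 and 452 in posterior midgut, and 387 and 293 in hindgut. Between sections they were 407 (caeca, anterior midgut), 239 (caeca, posterior midgut), 587 (caeca, hindgut), 285 (anterior, posterior midgut), 887 (anterior midgut, hindgut) and 605 (posterior midgut, hindgut). Then 77 were highest in caeca, 9 in anterior midgut, 10 in posterior midgut and 314 in hindgut, and 0 were higher than whole larvae in all sections.

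Array weights were 0.19 for anterior midgut array 2, the lowest, 0.357 for its array 3 and 4.27 for its array 1. The weighted anterior midgut mean thus rested mostly on array 1. With these weights, 1225 differed between caeca and anterior midgut, 641 between caeca and posterior midgut and 835 between anterior and posterior midgut. Then 214 were highest in caeca, 108 in anterior midgut and 47 in posterior midgut, and 85 were higher in all sections. The cause was not tested.

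The study's design names a plain t-test at 2-fold. Unadjusted, the methods' t-test gave 762 higher and 584 lower in caeca, 306 and 961 in anterior midgut, 647 and 757 in posterior midgut and 1251 and 541 in hindgut, sharing 1220, 1261, 1313 and 1695 probe sets with limma. After adjustment it gave 98 and 97, 2 and 19, 71 and 178, and 695 and 206, with 0 in all sections. limma on the compared groups gave 161 and 536 in anterior midgut and 17 higher in all sections. Both use only those fewer arrays for the spread.

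Leaving out 1 array in turn gave 309 to 647 higher in anterior midgut, 594 to 1775 between caeca and anterior midgut, 400 to 1304 between anterior and posterior midgut, 38 to 204 highest in anterior midgut and 17 to 30 in posterior midgut, and 33 to 96 higher in all sections. The highest values came without anterior midgut array 3, apart from 96, which came without its array 2; 17 came without posterior midgut array 2 and 33 without whole-larva array 1. The cause was not tested.

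Against the number-ID background, 6958, 4676, 6005, 7185 and 7612 probe sets were above background in caeca, anterior midgut, posterior midgut, hindgut and whole larvae, against 15948, 15906, 15852, 15662 and 16231 by the Pf background. The number-ID background itself lay highest in anterior midgut, where its count was lowest.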

Other observations

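The counts of probe sets close in ID number, the splits within replicate numbers and the subsets of midgut arrays were chosen as tests after the data were seen.

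Most of the probe sets low in caeca were also low in the midgut sections. Of the 659 probe sets lower in caeca than in whole larvae, 581 were also lower in anterior midgut, 554 in posterior midgut and 340 in hindgut. Independent lists would share 52.4, 34.1 and 26.7. The lists of the latter sections differ in length (1343, 873 and 683) and all use the same whole-larva arrays. These counts therefore do not rank the sections by their likeness to caeca. The most frequent class of lower probe sets in more than a single section was lower in all 4 (302), followed by lower in caeca, anterior and posterior midgut without a call in hindgut (187). Among probe sets called in both directions, 34 were higher in hindgut and lower in the other 3 sections, and 26 were higher in caeca and lower in the other 3.

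Whole-larva arrays varied more than most sections for some of the probe sets with the largest rises. Ag.2L.586.1_a_at had an SD of 2.37 log2 units in whole larvae (n = 3) and 0.81 in caeca, Ag.3R.2365.0_CDS_at 2.46 in whole larvae and 0.96 in posterior midgut, and Ag.3L.257.0_CDS_at 1.98 in whole larvae and 0.09 in hindgut. The folds given for Ag.2L.586.1_a_at and Ag.3L.257.0_CDS_at rest on whole-larva means with that spread.

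Probe sets with adjacent ID numbers under the same arm token may have similar profiles over the 5 groups. The mean correlation over 4221 adjacent pairs was 0.142, above the highest of 1000 permutations of the numbers within arms, 0.0846, which is what ID numbers that follow position and neighbours that share expression would give. Signal shared between probe sets of related sequence, as all of the pattern, is argued against by probe sets of the plain _at type alone, with 0.136 against a highest permutation of 0.0979. The correlation was still 0.123 at a distance of 10 numbers, so it was not particular to direct neighbours, and no source used here says how the numbers were given. Pairs of stems within 2 numbers, both highest in the same section, numbered 115 in hindgut against a permutation mean of 76.7 and 9 in caeca against 2.34 (permutation p = 0.001 each, the smallest these permutations can give, adjusted p = 0.002). Anterior midgut had 3 against 0.37 (permutation p = 0.009, adjusted p = 0.012) and posterior midgut 0 against 0.071 (permutation p = 1).

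Other splits of the arrays were compared with the real groups. For each of the 10 contrasts, 6 arrays make 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, reached the real count in each, and the highest other count was 2 for caeca against whole larvae (real count 1375), 5 for anterior midgut (1739), 1 for posterior midgut (1501), 6 for hindgut (1913) and 0 in all 6 contrasts between sections (413 to 2551, with the same fit in limma).

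For probe sets highest in a section, 100 splits of the 12 section arrays were drawn, the real one included. For caeca 1 split gave as many as the real 136 (highest other 0) and for hindgut 1 gave as many as the real 814 (highest other 86). For anterior midgut 2 splits did (real 54, highest other 789) and for posterior midgut 2 did (real 26, highest other 82). These splits ask whether all 12 arrays can be exchanged, which hindgut or caeca arrays alone may break. The split with 789 put the 3 hindgut arrays together under another name, and those with 82 and 86 did so with the 3 caeca arrays, which points to the structure of the samples.

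Same-numbered arrays of caeca and posterior midgut were taken as paired, so 100 splits that kept each replicate number once per group were drawn as well. With the real one included, 4 of these splits gave as many as the real count for caeca, 2 for anterior midgut, 6 for posterior midgut and 2 for hindgut. The 6 of 100 for posterior midgut is not a share under 0.05. The highest others, 827, 808, 818 and 823, all had the 3 hindgut arrays together, so groups that held all 3 arrays of a section were set aside. Groups that mixed sections then gave 0 in both kinds of splits. Mixed groups also widen the spread and so lower their counts, and the other groups that reached the real counts had been set aside. These splits therefore do not decide whether a chance assignment of the 12 arrays could give such counts. With caeca and hindgut arrays held, the 6 midgut arrays give 20 subsets, too few for a share under 0.05. The real ones gave 54 and 26, and subsets that mixed the midgut sections gave 0. For posterior midgut 2 subsets reached the real count, the real one and the 3 anterior midgut arrays under that name.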
